A study of Arabidopsis thaliana with 8 samples.

How the data were processed

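Transcript levels were measured in shoots of Arabidopsis thaliana seedlings on Affymetrix ATH1 arrays, which read each transcript with a set of short oligonucleotide probes (a probe set). All 8 arrays come from the gibberellin-deficient mutant ga1-3 in the Ler background. Per the labels, seedlings aged 8 days, grown upright at 22 °C in continuous light on medium with 2% sucrose, were sprayed with water or with 2 µM GA4, a bioactive gibberellin, and shoots were cut off 1 h later. RNA was extracted from 100 mg of tissue and labelled with biotin. The labels name 4 biological replicates per treatment, numbered 1 to 4 in each group, and do not say what a shared number marks. There was no untreated or wild-type sample, so the water arrays served as the control.

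The deposited table holds 1 MAS5 signal intensity per probe set and array on a linear scale, and MAS5 is named without a version in the submitters' processing notes. The 2%-trimmed means of the 8 deposited columns ran from 500.04 to 500.05, within the 5% tolerance set for using the signals without rescaling, so no further scaling was applied. The table has 22810 probe sets, of which 64 are array controls that were left out of the tests. Signals below 1 (707 of 182480 values) were set to 1 before taking log2. The 60% of the remaining 22746 probe sets with the highest mean log2 signal over all 8 arrays were tested, which kept 13648 with a mean signal of at least 110 units. No detection calls were used, so a low value cannot be told from background. The number of arrays, 4 per group, limits the precision.

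Gene names came from the platform annotation supplied with the data, updated through the TAIR10.1 gene table. It gave 1 gene for 13513 of the 22746 probe sets (13436 matched to a locus), several genes for 503 and listed no gene for 8730. Probe sets of the last 2 kinds are given by their identifier only. Of the tested probe sets, 7337 had 1 gene. The array's annotation carries no genome build, so positions are not given.

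GA4 was compared with water by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with a mean-variance trend on the log2 signals, 2-sided, with Benjamini-Hochberg adjustment over the 13648 probe sets and a threshold of 0.05. Fold changes are GA4 minus water on the log2 scale. The planned fit had no block. The planned check of the replicate numbers took each array's deviations from its group mean over the tested probe sets. Arrays with the same number correlated at 0.616 to 0.685 in all 4 pairs, above the minimum of 0.1 set for calling them paired, and 8 of 8 arrays correlated better with the array of their own number than with the other arrays of the other treatment. Among all arrays, GA4 replicates 3 and 4 correlated best with each other (0.709). Across treatments, arrays of different number also exceeded 0.1 within replicates 1 and 2 (0.367 and 0.392) and replicates 3 and 4 (0.544 and 0.599). That minimum therefore cannot tell pairing by number from a difference of replicates 1 and 2 from 3 and 4. The pairing comes from the best matches by number and from the numbers in the labels. Between the sets these correlations were all negative, so each array had only 1 real rival to its own number. The best matches are therefore weak evidence, and pairing by number is not established over a block on the 2 sets. Results are given from the planned fit (unpaired fit) and, where the call or count differs, from the fit with the replicate number as a block (paired fit). The median residual SD was 0.342 log2 units unpaired and 0.201 paired.

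Before the data were examined, 28 gene lists of 368 distinct loci were fixed for gibberellin metabolism and signalling, growth, other hormones, stress, development and reference genes. Only 59 of the loci had a probe set named here, and 43 were tested. Lists with at least 3 tested members, 6 of the 28, were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, using 1 probe set per gene, and again with an estimated correlation. The same lists were tested with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. The rule for naming genes was also fixed then. It took every member of 3 gibberellin lists and, because fewer than 20 probe sets passed the unpaired fit, the 12 smallest unadjusted p in each direction. Taking those 24 only among probe sets with 1 gene, and adding the calls of the paired fit with 1 gene that moved the same way in all 4 pairs (at most 12 per direction), were chosen after the values were seen. No named gene had another named probe set (0 of 37).

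The code was tested on simulated data built from the level of each replicate pair and the residual spread of the paired fit, for the 13648 probe sets. Noise was drawn independently for each probe set. The simulation thus assumed the pairing, so its comparison of the fits is no evidence for the paired fit. Of 100 probe sets changed by 1 log2 unit, the unpaired fit recovered 25% and the paired fit 65%. Of 100 changed by 2 log2 units they recovered 79% and 93%. The unpaired and paired fits called 0 and 5 unchanged probe sets. The arrays were also compared by principal components (R's prcomp), by the 3′ to 5′ signal ratios of control transcripts and by 9 probe sets for hybridisation controls, which are labelled transcripts spiked into the sample before hybridisation. These were compared between sets of 4 arrays by 2-sided exact permutation tests over 70 splits, whose smallest possible p is 0.0286.

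The results were computed again with quantile normalization, median centring, log2(signal + 16), a floor at the 20th percentile, no filter, the 40% brightest probe sets, eBayes without a trend or with a robust prior, array weights, the replicate block, leaving out each array, an adjusted p of 0.10 and a minimum of 1.5-fold. Figures were drawn with matplotlib 3.10.9.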

Results

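The study set out to find genes that respond early to gibberellin, a growth hormone that acts through the GID1 receptors and the breakdown of DELLA repressor proteins. Shoots of the gibberellin-deficient mutant ga1-3 were compared 1 h after a spray with 2 µM GA4 (4 arrays) or water (4 arrays). Of the 22746 probe sets on the array that were not controls, 13648 were bright enough to be tested. Every array had a trimmed mean signal of 500.04 to 500.05, and the median signal ran from 163 to 223.

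The arrays of replicates 1 and 2 stood apart from those of replicates 3 and 4 in both treatments. The first principal component held 60.0% of the variance and separated these sets of 4 arrays. Correlations of log2 signals were at least 0.976 among the arrays of replicates 3 and 4, 0.923 to 0.955 among those of replicates 1 and 2, and at most 0.926 between the sets. The 3′ to 5′ signal ratio of actin was 2.72 to 6.81 on replicates 1 and 2 and 1.5 to 1.76 on replicates 3 and 4, and that of GAPDH was 2.13 to 5.43 against 0.958 to 1.14 (exact permutation p = 0.0286 for each, adjusted p = 0.0429 over 6 measures). The ratio of ubiquitin overlapped, with 1.30 to 2.80 against 1.32 to 1.59 (exact permutation p = 0.143, adjusted p = 0.171). The median signal was 203 to 223 on replicates 1 and 2 and 163 to 173 on replicates 3 and 4. The lower quartile was 51.4 to 77.2 against 39.5 to 45.4 (exact permutation p = 0.0286 and adjusted p = 0.0429 for each). The spiked hybridisation controls were at 2.87 and 1.71 times the water mean on GA4 replicates 1 and 2 and at 0.941 to 1.16 times on the other 6 arrays (exact permutation p = 0.0571 for GA4 against water). Within replicates 1 and 2 the ratios were higher on the GA4 than on the water array for all 3 control transcripts (actin 6.81 against 5.07 and 4.48 against 2.72, GAPDH 3.5 against 2.25 and 5.43 against 2.13, ubiquitin 2.80 against 2.52 and 2.30 against 1.30). Within replicate 3 they were higher on GA4 for actin and GAPDH only (1.58 against 1.5 and 0.980 against 0.958), and within replicate 4 for none. Each set held 2 arrays of each treatment, so values within each set are given below for GID1A, XERICO and the genes named by the rule whose GA4 effect differed most between them.

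**Figure D1:**
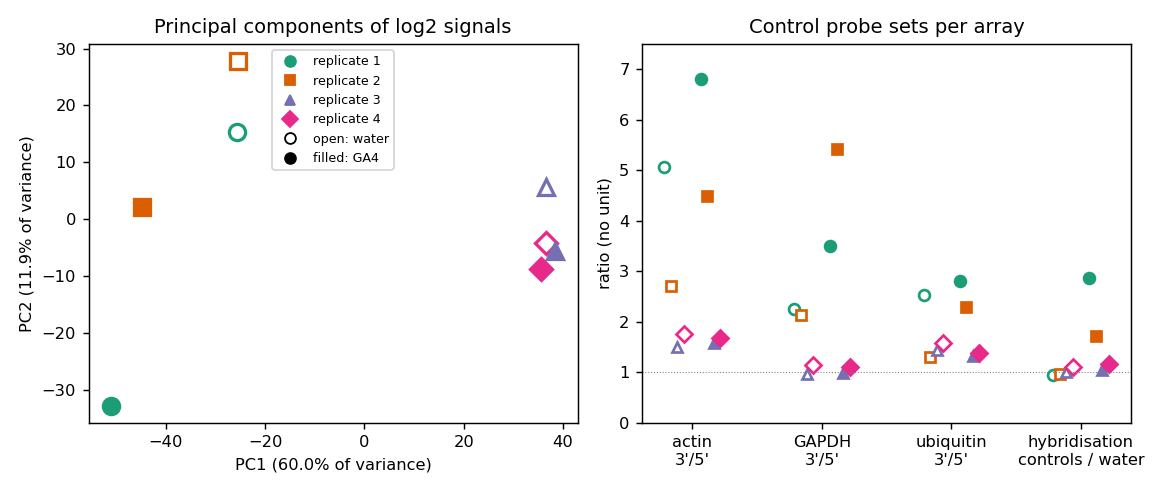
Left, the first and second principal components of the log2 signals of 8 arrays (symbols are replicate numbers, open for water, filled for GA4). Right, the 3′ to 5′ signal ratios of 3 control transcripts and the hybridisation controls as a fold of the water mean, per array. Replicates 1 and 2 lie on one side of the first component, and GA4 replicates 1 and 2 have the brightest hybridisation controls, at 2.87 and 1.71 times the water mean.

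Shoots sprayed with GA4 held less transcript of the gibberellin receptors GID1A and GID1B than water-sprayed shoots once arrays were paired by replicate number. GID1A fell by 1.61 on the log2 scale (3.05-fold, paired SE 0.20, n = 4 pairs) and GID1B fell by 1.44 (2.71-fold, SE 0.24), each in 4 of 4 pairs. XERICO, a RING-type protein tied to abscisic acid accumulation, fell by 1.58 (2.99-fold, SE 0.16). The transcript of AT1G68570, which carries the synonym NPF3.1 and belongs to a family of nitrate and peptide transporters, fell by 0.93 (SE 0.14, adjusted p = 0.0232 paired and 1.00 unpaired). Among the calls whose mean signal stayed above the filter level in both groups, probe set 261768_at, which has no gene listed here, had the largest drop. It fell by 3.26, or 9.55-fold, from 10.94 ± 0.41 to 7.69 ± 0.47 (mean log2 signal ± SD, n = 4).

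In the unpaired limma fit, 2 of the 13648 probe sets passed the threshold, and both were lower in GA4. These were 261768_at (SE 0.28, adjusted p = 0.00487) and 261866_at, also without a listed gene, which fell by 1.71 (SE 0.19, adjusted p = 0.0292). In the paired fit 40 passed, 35 lower and 5 higher in GA4, among them both calls of the unpaired fit. Of these 40, 16 had 1 gene listed (13 lower, 3 higher), 1 had several and 23 had none. At an unadjusted p under 0.05 there were 361 probe sets unpaired (241 lower) and 1611 paired (905 lower). By chance a share of 0.05 of the 13648 tests would lie there, which is more than 361 and fewer than 1611. Adjusted p values for GID1A were 0.0856 unpaired and 0.00929 paired, for XERICO 0.121 and 0.00236, and for GID1B 1.00 and 0.0419. Leaving out any 1 of the 8 arrays left 1 call, 261768_at, in the unpaired fit. Without replicate pair 1 the paired fit called 17 probe sets and without pair 2 it called 8, while GID1A had adjusted p of 0.00476 to 0.111 over 12 alternatives and passed in 10 of them. It did not pass without pair 1 (adjusted p = 0.0607) or without pair 2 (adjusted p = 0.111). GID1B passed in 6 of 12 (adjusted p 0.00419 to 0.149) and did not pass when any 1 of the 4 pairs was left out (adjusted p of 0.0645, 0.149, 0.0796 and 0.105 without pairs 1 to 4). XERICO passed in 13 of 13 (adjusted p 2.9e-04 to 0.0345).

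**Figure D2:**
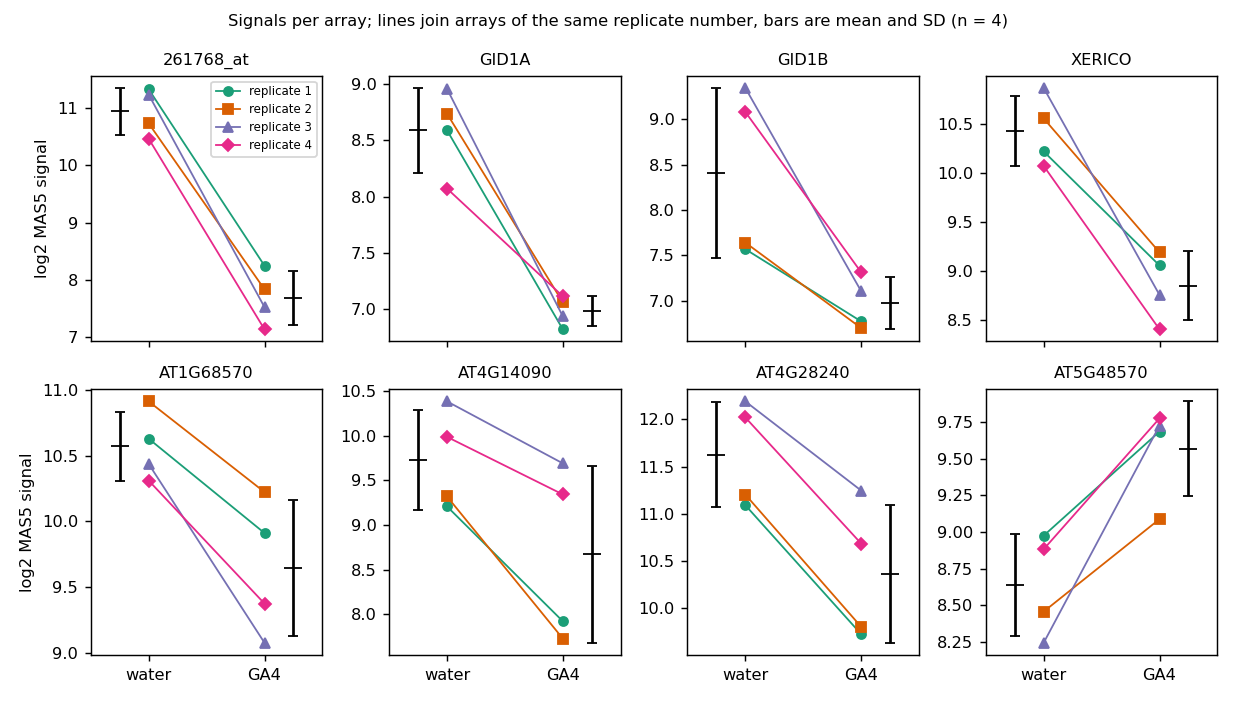
Log2 MAS5 signal of 8 probe sets on each array, with lines joining arrays of the same replicate number and bars for the mean and SD of 4 arrays. In each panel all 4 lines run the same way, down in 7 panels and up for AT5G48570, and the water level of GID1B is 7.57 and 7.64 on replicates 1 and 2 and 9.35 and 9.08 on replicates 3 and 4. For AT1G68570, AT4G14090 and AT4G28240 the same direction in all 4 pairs was a condition of being named.

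Within replicates 3 and 4 alone, 9 probe sets passed, all lower in GA4, and 8 of them were among the 40 paired calls. Within replicates 1 and 2 alone, only 261768_at passed. GID1A was lower by a mean difference of −1.72 on replicates 1 and 2 and −1.49 on replicates 3 and 4, XERICO by −1.27 and −1.89, and GID1B by −0.87 and −2.01. The GID1B signal on GA4 replicates 1 and 2, at 6.77 and 6.70 log2, lay below the filter level of 6.78, so the size of −0.87 is uncertain. Other genes named by the rule with large differences between the sets were AT1G24530 at −1.51 and −0.33, AT4G14090 at −1.44 and −0.67, AT5G24460 at 1.12 and 0.30 and HHP2 at 1.05 and 0.33. Outside the rule, and chosen after the values were seen, the paired call 245136_at was at −2.64 and −0.89. No probe set passed a limma test of the difference in GA4 effect between these sets (0 of 13648, smallest adjusted p = 0.294, 957 at an unadjusted p under 0.05). By chance a share of 0.05 of these tests would lie there, which is fewer than 957. With 2 arrays per treatment in each set, the lack of calls does not show that the effect was the same in both. Of the 50 lower probe sets with the smallest p on replicates 1 and 2, 42 (84%) were also lower on replicates 3 and 4, against 48.6% of all tested. Of the 50 higher ones, 29 (58%) were higher on replicates 3 and 4, against 51.4% of all tested. Chosen on replicates 3 and 4 instead, 50 of 50 lower probe sets were lower on replicates 1 and 2 (49.2% of all tested) and 35 of 50 higher ones (70%) were higher (50.8% of all tested). The median fold change of the 50 lower ones chosen on replicates 1 and 2 was −1.59 there and −0.47 on replicates 3 and 4. For those chosen on replicates 3 and 4 it was −1.05 there and −1.03 on replicates 1 and 2. Over all tested probe sets the fold changes of the sets correlated at only 0.187 (Pearson) and 0.112 (Spearman).

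Among the other genes that fell in the paired fit was AT4G14090, a glucosyltransferase of the anthocyanin branch, by 1.05 (SE 0.17, adjusted p = 0.0349). SCPL45, a serine carboxypeptidase-like protein, fell by 0.91 (SE 0.14, adjusted p = 0.0335). AT5G18840, a sugar transporter of the major facilitator superfamily, fell by 1.03 (SE 0.13, adjusted p = 0.0119), and AT5G47550, a cystatin (an inhibitor of cysteine proteases), fell by 0.82 (SE 0.11, adjusted p = 0.0127). AT4G28240, a protein of a wound-responsive family, fell by 1.26 (SE 0.12, adjusted p = 0.00210). AT1G54120 fell by 1.41, AT5G17760 by 1.19 and AT4G37240 by 1.07, with adjusted p of 0.0458, 0.0132 and 0.00894. Each was lower in 4 of 4 pairs, which the rule required for naming calls of the paired fit. In the unpaired fit the adjusted p was 0.130 for AT5G18840 and 1.00 for the other 7. Over the alternatives of the paired fit AT4G28240 passed in 13 of 13, AT4G37240 in 12 of 13, AT5G18840 in 11 of 13, AT5G47550 in 10 of 13 and AT5G17760 in 10 of 12. AT1G68570 passed in 9 of 13, AT4G14090 in 8 of 13, SCPL45 in 6 of 13 and AT1G54120 in 5 of 12. With quantile normalization the adjusted p was 0.0818 for AT4G14090, 0.0619 for SCPL45 and 0.128 for AT1G54120. The probe sets 266912_at and 248371_at, without a listed gene, also passed in the paired fit. Their geometric mean signals in GA4 were 45.1 and 64.0 units, below the 110 units of the filter, where a value cannot be told from background, so no size is given for these drops.

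The 3 genes that rose in the paired fit were AT5G48570, AT3G51660 and AT4G04010, with none past the threshold unpaired. None of the 3 passed with the block on replicate sets in place of the replicate number. These calls therefore rest on pairing by number, which is not established over that block. AT5G48570, the heat-inducible peptidyl-prolyl isomerase ROF2, rose by 0.93 (SE 0.16, adjusted p = 0.0411). AT3G51660, which encodes a protein resembling macrophage migration inhibitory factor, rose by 0.73 (SE 0.12, adjusted p = 0.0411). AT4G04010, a pseudogene whose probe set is of a type that can bind related transcripts, rose by 1.20 (SE 0.20, adjusted p = 0.0411). Its water signals on replicates 3 and 4, at 5.95 and 6.47 log2, lay below the filter level of 6.78, so this size is uncertain. After quantile normalization the paired fit called 20 probe sets, 20 lower and 0 higher. The fold changes of the 3 genes were then 0.93, 0.75 and 1.19, with adjusted p of 0.0588, 0.0614 and 0.0676. Over all alternatives of the paired fit AT5G48570 passed in 5 of 13, AT3G51660 in 5 of 13 and AT4G04010 in 6 of 12.

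**Figure D3:**
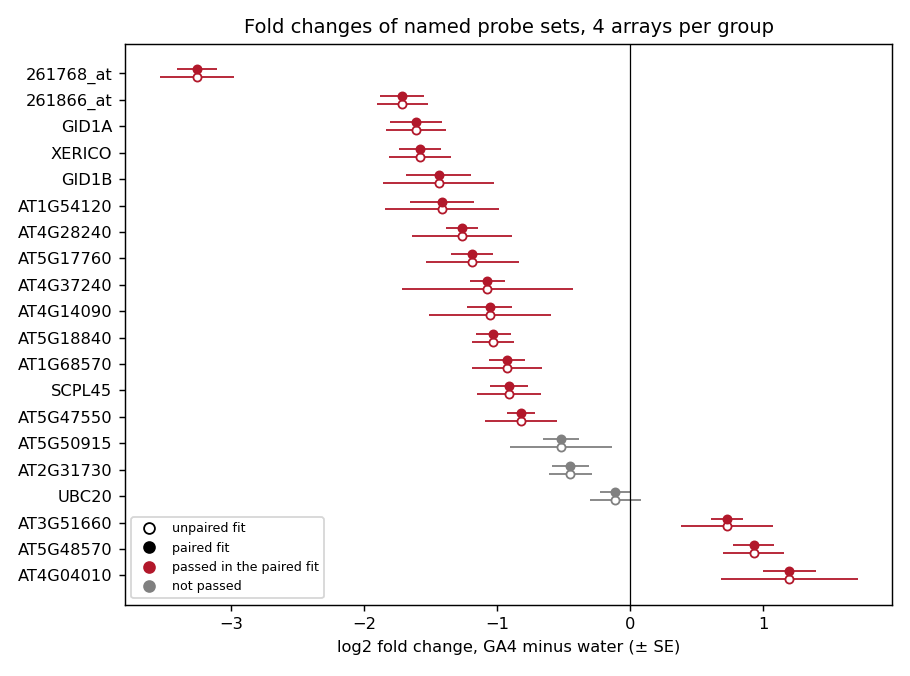
Log2 fold change of GA4 minus water with its SE for the probe sets that passed in either fit and are named by the rule, and for the tested targets the study named (4 arrays per group; open circles unpaired, filled circles paired; red passed in the paired fit). The lower probe sets run from −3.26 to −0.82, and those of AT5G50915, AT2G31730 and UBC20, which did not pass, from −0.52 to −0.11.

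Of the list of gibberellin metabolism and signalling genes, 6 of 33 members had a named probe set and 5 were tested. None passed unpaired among all genes tested, and 2 (GID1A and GID1B) fell in the paired fit. Adjusted over the list alone, 3 passed in each fit. The additional one was SLY1, the F-box protein that targets DELLA proteins, at −0.65 (paired SE 0.18), while SNE at −0.20 and SPY at −0.05 did not pass. SLY1 was at −1.35 in pair 3 and between −0.50 and −0.34 in the others. The list as a whole was lower than other genes by camera (adjusted p = 7.1e-07 unpaired, with adjusted p = 0.00927 with an estimated correlation). In the paired fit these were 1.5e-04 and adjusted p = 0.260 with an estimated correlation. fry, which asks whether a list's genes move one way and makes no comparison with other genes, gave an adjusted p of 0.00440 unpaired and 0.0697 paired. GID1A and GID1B were also the only tested members of the list of feedback-regulated genes, and both passed when adjusted over the list alone in each fit. Both also belong to the targets the study named, which were chosen partly on these samples. Their falls are therefore no independent evidence in any of these lists. GID1C, the remaining receptor, lay below the filter at 6.54 ± 0.38 in water and 6.59 ± 0.10 in GA4 (mean log2 signal ± SD, n = 4). None of the 7 gibberellin 2-oxidases, which inactivate gibberellins, had a named probe set.

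The list of DELLA targets named by the study was chosen partly on these samples and is not independent evidence of its direction. Of its 14 members 6 were tested, and GID1A, GID1B and XERICO fell in the paired fit. The bHLH genes AT5G50915 (bHLH137) and AT2G31730 (bHLH154) were at −0.52 (paired SE 0.14) and −0.45 (SE 0.14), and the ubiquitin-conjugating enzyme UBC20 was at −0.11 (SE 0.12). Adjusted over the list alone, 4 passed unpaired and 5 paired, against 0 and 3 among all genes tested. The list was lower by camera, with adjusted p = 3.0e-11 unpaired (adjusted p = 0.00239 with an estimated correlation) and 4.3e-08 paired (adjusted p = 0.105 with an estimated correlation). By fry the adjusted p was 3.8e-04 unpaired and 0.0170 paired.

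The cell wall lists gave no call in single genes. The 7 tested expansins, which loosen cell walls, had a median of 0.01, with EXPA8 at 0.53 (paired SE 0.19) and EXPA16 at −0.37 (SE 0.28), and their list did not pass (camera adjusted p = 0.733 unpaired, 0.567 paired). The 6 tested XTH genes, which cut and rejoin xyloglucan, had a median of −0.35 and passed by camera in the paired fit only (adjusted p = 0.0362, adjusted p = 0.280 with an estimated correlation), but not by fry (adjusted p = 0.768 unpaired, 0.184 paired). Over the alternatives of the paired fit the list passed in 8 of 13 (adjusted p 0.0103 to 0.170), and not with quantile normalization, no filter or array weights, or without pair 1 or pair 2. XTH27 was at −0.52 (paired SE 0.14), and 1 of the 6 passed adjusted over the list alone. On replicates 3 and 4 alone the median of the XTH list was 0.02, and XTH19 was at −1.23 on replicates 1 and 2 and 0.26 on replicates 3 and 4. GASA7 and GASA9, of a gibberellin-regulated family, were at 0.24 (paired SE 0.12) and 0.16 (SE 0.11).

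The lists of touch, wounding and early stress genes and of flavonoid and anthocyanin genes gave no call among all genes tested. The first of these held ZAT10 at −0.47 (paired SE 0.11), CML38 at −0.68 (SE 0.18) and WRKY53 at 0.27 (SE 0.22), of which 0 passed unpaired and 2 paired when adjusted over the list alone. It did not pass by camera (adjusted p = 0.426 unpaired, 0.0606 paired), but passed fry's test for a shift one way in the paired fit (adjusted p = 0.0456, 0.768 unpaired). DFR and UF3GT, enzymes of anthocyanin synthesis, were at −0.61 (paired SE 0.12) and −0.71 (SE 0.16), and both passed adjusted over the list alone in each fit. Of the other tested list members, HAT2, a homeodomain gene of the shade response, was at −0.67 (paired SE 0.12, adjusted p = 0.0589), SIM, a cell cycle inhibitor, at −0.43 (SE 0.15, adjusted p = 0.325) and GIS, a trichome regulator, at 0.60 (SE 0.15, adjusted p = 0.148). Each was the 1 tested member of its list. The remaining ones, from auxin, cytokinin, abscisic acid, clock, greening and glucosinolate lists, were between −0.31 and 0.46 and did not pass.

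The reference genes UBC21, SAND and TIP41L were at 0.26, 0.01 and 0.22, and their list did not pass (camera adjusted p = 0.230 unpaired, 0.164 paired). The root markers EXPA7 and EXPA18 lay below the filter, at mean log2 signals of 6.27 and 5.41 in water and 6.59 and 6.08 in GA4, as did the shoot apex marker CLV3 at 2.83 and 2.94. In all, 6 of the 28 lists could be tested as lists, 12 had fewer than 3 tested members and 10 had none. Of the 6, 2 passed unpaired by camera and 3 paired. With an estimated correlation 2 passed unpaired and 0 paired.

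The genes with the smallest unadjusted p in the unpaired fit that passed in neither fit are given as values only. On the lower side AT3G15570 was at −1.46, AT3G55350 at −1.03, AT1G24530 at −0.92, AT1G17830 at −0.89 and AT1G71970 at −0.81. AT5G40540, AT4G27300 and AT3G52500 were at −0.76, −0.70 and −0.60. On the higher side AT2G38090 was at 0.87, AT2G18590 at 0.74, AT5G15360 at 0.74 and AT1G49470 at 0.72. AT5G24460, HHP2, AT2G28660, AT1G76240, AT2G21185, AT5G45670 and AT5G27490 were between 0.47 and 0.71. Their paired adjusted p ran from 0.0531 to 0.249. For AT3G15570 and AT3G55350 the geometric mean signal in GA4 (70.2 and 80.0 units), and for AT2G38090 and AT2G18590 that in water (98.2 and 105 units), lay below the filter, so the sizes of these 4 differences are uncertain.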

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

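The tests on the arrays of replicates 1 and 2 and the tests of less labelled target and of a stronger 3 prime bias on GA4 replicates 1 and 2 were chosen after the results were seen, as were the values within replicate sets.

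In 2 of 90 groups of 4 values examined, 1 array lay far from the others, where chance gives this in about 5% of groups. AT5G48570 on GA4 replicate 2 was at 9.09 against 9.68 for the nearest GA4 array (gap over range 0.869), and AT1G71970 on GA4 replicate 4 was at 8.29 against 7.96 (gap over range 0.880). The hybridisation controls, which enter no comparison of genes, were 2.87 times the mean of the water arrays on GA4 replicate 1 and 1.71 times on GA4 replicate 2, above the highest water array at 1.10.

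The arrays of replicates 1 and 2 stand apart from those of replicates 3 and 4, and splitting the 8 arrays this way called 5413 probe sets in the unpaired fit. Less labelled target on all 4 arrays of replicates 1 and 2 is argued against. The hybridisation controls were brighter than on every array of replicates 3 and 4 on only 2 of the 4 arrays. The median and lower quartile of the signals also separated the sets, and whether this reflects labelled target was not tested. A stronger 3 prime bias of the RNA or its labelling in replicates 1 and 2 may contribute. The 3′ to 5′ ratio was higher on all 4 arrays of replicates 1 and 2 for 2 of 3 control transcripts, but that of ubiquitin overlapped, which keeps this open. The design names no difference between the replicate numbers, so no biological explanation was tested.

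Most calls of the paired fit, 35 of 40, are lower in GA4. On replicates 1 and 2 the GA4 arrays had brighter hybridisation controls and higher 3′ to 5′ ratios for all 3 control transcripts than the water array of the same number, so less labelled target or a stronger 3 prime bias on GA4 replicates 1 and 2 may contribute. Each is argued against as the whole cause. Of the 50 strongest lower probe sets of those replicates, 84% were also lower on replicates 3 and 4. These measures were nearly even there, and all 9 calls were lower. The size of the drop was smaller there, with a median of −0.47 for these 50 against −1.59 on replicates 1 and 2, so a partial contribution stays open. After quantile normalization 100% of the 20 calls in the paired fit were lower. That share decides little about scaling, since the 3 genes that rose kept fold changes of 0.93, 0.75 and 1.19 and only missed the threshold. The median fold change of all tested probe sets was 0.008 as deposited, 0.003 after quantile normalization and −0.023 after median centring. Each of these scalings evens out the arrays and holds this median near 0, so it cannot decide about scaling. After quantile normalization 261768_at, GID1A and XERICO were at −3.24, −1.69 and −1.54 in the paired fit, close to their values as deposited. For the other calls the part of scaling stays open. An early loss of the transcripts called lower after GA4 stays open as a hypothesis, found and examined on the same data.

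Other splits of the arrays were compared with the real one. In the unpaired fit 2 of 35 splits gave as many calls as the real 2, the other being the split of replicates 1 and 2 from 3 and 4 with 5413, a structure of the samples that the paired fit and the values within replicate sets leave out. These splits ignore the pairing. Of the 8 splits that part all 4 pairs, 1, the real one, gave as many as 2 calls in the unpaired fit and 1, again the real one, gave 40 in the paired fit, and the highest of the others, which swap the treatments within some pairs, gave 0 in each. With 8 splits no share under 0.05 can be reached. For the gene lists, 12 of 35 splits gave as many as the real 2 in the unpaired fit and the highest of the others gave 5, so chance is not excluded for that number of lists.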

How the results depend on the processing

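The block on replicates 1 and 2 against 3 and 4, the values within those sets, the omission of GA4 replicates 1 and 2, and every combination with the replicate block were chosen after seeing the data. The unpaired fit's 2 calls (0 higher, 2 lower) stayed at 2 or 3 with quantile normalization, median centring, either floor, no trend, a robust prior or a minimum of 1.5-fold. They became 1 (1 lower) without the filter or with the 40% brightest probe sets, 8 (8 lower) with array weights and 5 at an adjusted p of 0.10. With the replicate block they became 40 (5 higher, 35 lower), with the block on replicate sets 32 (1 higher, 31 lower, 30 shared with the paired fit), and without GA4 replicates 1 and 2 with that block 9 (9 lower). Replicates 3 and 4 alone gave 9 (9 lower) and replicates 1 and 2 alone gave 1 (1 lower). Leaving out any 1 array gave 1 call (1 lower). The 2 lists past the threshold became 1 with the 40% brightest probe sets, where fewer lists could be tested, and 4 on replicates 3 and 4 alone. The paired fit's 40 calls became 20 (0 higher, 20 lower) with quantile normalization, 21 (1 higher, 20 lower) without the filter, 11 (0 higher, 11 lower) without a trend, 99 (20 higher, 79 lower) with array weights and 112 at an adjusted p of 0.10. Median centring left 31, with 2 higher, and the 40% brightest probe sets 27, with 23 lower. Leaving out 1 replicate pair gave 8 to 51 calls, with 0 to 4 higher and 8 to 50 lower: 17 without pair 1, 8 without pair 2, 51 without pair 3 and 42 without pair 4, of which 16, 8, 29 and 28 were shared with the 40. With an estimated correlation 0 lists passed in the paired fit, against 3 with the preset. The leave-out fits had fewer samples, and the fit without the filter had more tests. Fewer samples alone do not explain the leave-out counts, since they rose to 51 without pair 3 and 42 without pair 4. The cause of these and the other shifts was not tested. The replicate block kept the calls of the 2 unpaired probe sets and, by camera with the preset correlation, changed the call of no list but XTH. With an estimated correlation it ended both list calls (adjusted p 0.00927 to 0.260 for gibberellin metabolism and signalling, 0.00239 to 0.105 for the targets the study named). By fry the first of these lists went from 0.00440 to 0.0697 and the touch, wounding and early stress list from 0.768 to 0.0456. None of the 39 probe sets named by the rule changed direction under the alternatives that tested it. Each had moved one way in all 4 pairs, so leaving out pairs, fitting a set alone or adding a block could not have reversed it. For those alternatives the lack of a change is no evidence of stability. Other list members were not refitted gene by gene. Of all 43 tested list members, 13 had opposite signs on replicates 1 and 2 and on replicates 3 and 4, none of them named by the rule. Examples were SNE (0.24 and −0.64) and EXPA16 (−0.85 and 0.11). XERICO, AT4G28240, 261768_at and 261866_at passed in all alternatives of the paired fit. The median of the XTH list was 0.14 with array weights and 0.12 without GA4 replicate 2. Without detection calls, signals near the filter at 110 units have no measured background to set them against.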

Other observations

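Both hypotheses below came from genes seen in these data, and the added gene lists were chosen after those values were seen. The expected outcome for the members not yet looked at was set before their values were seen.

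Anthocyanin genes may fall together after GA4. DFR at −0.61, UF3GT at −0.71 and AT4G14090 at −1.05 led to the test, and of 2 further enzymes of this branch, UGT78D2 at −0.37 (paired SE 0.14) and AT5MAT at −0.44 (SE 0.20), 2 were lower in all 4 pairs. Neither passed alone (limma paired adjusted p = 0.360 and 0.419). UGT78D2 was at −0.90 in pair 2 and between −0.27 and −0.11 in the others, and AT5MAT was at only −0.04 in pair 4. On replicates 1 and 2 and on replicates 3 and 4, AT4G14090 was at −1.44 and −0.67 and UF3GT at −0.995 and −0.42. UGT78D2 was at −0.50 and −0.23, AT5MAT at −0.53 and −0.35 and DFR at −0.60 and −0.61. The fall was thus larger on replicates 1 and 2 for all but DFR. On those replicates the GA4 arrays also had higher 3′ to 5′ ratios and brighter hybridisation controls than the paired water arrays. Whether these added to the fall was not tested. The 5 genes as a list were lower by camera with an estimated correlation (adjusted p = 0.00444 unpaired and 0.0473 paired), but 3 of them had been picked for their fall.

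Heat-shock genes may rise together after GA4, as AT5G48570 did in the paired fit. Of 9 further heat-shock genes 5 were tested, and all 5 had values above 0, with a median of 0.52 that lay at percentile 100 of 10000 random lists matched on mean signal. Random lists need not vary together as these genes and AT5G48570 did (estimated correlation 0.486 unpaired, 0.584 paired), so this percentile overstates the support. Among them AT2G29500 was at 0.52, AT1G54050 at 0.53 and Hop3 at 0.47, and none passed alone. AT2G29500 (−0.42) and AT1G54050 (−0.01) were lower in pair 1, and AT2G20560 (−0.31) and Hop3 (−0.08) in pair 2. AT5G51440 was higher in 4 of 4 pairs. The list with AT5G48570, which had been picked for its rise, had a camera adjusted p of 0.0303 unpaired and 0.112 paired with an estimated correlation. By fry the adjusted p was 0.0374 unpaired and 0.0644 paired. The paired fit thus does not exclude that these genes merely vary together. The values lay mainly in replicates 3 and 4, with AT2G29500 at 1.19 there and −0.14 in replicates 1 and 2.

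GID1B was brighter in water on replicates 3 and 4 (9.35 and 9.08) than on replicates 1 and 2 (7.57 and 7.64), while its GA4 levels were 6.70 to 7.31 on all 4 arrays. The difference in its GA4 effect between these sets did not pass the limma test after adjustment over all probe sets (adjusted p = 0.683). On GA4 replicates 1 and 2 GID1B was at 6.77 and 6.70, below the filter level of 6.78, so the size of its effect there is uncertain.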
